A study of Arabidopsis thaliana with 6 samples.

How the data were processed

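RNA was sequenced from whole Arabidopsis thaliana seeds dissected from siliques at 6 days after pollination. Seeds came from self-pollinated Col-0 wild type (WT) plants and from plants carrying DD25::IaaH, whose background the labels also give as Col-0, each with 3 libraries described in the series' design text as biological replicates. IaaH is a bacterial hydrolase that makes auxin from indole-3-acetamide, and DD25 is the promoter that drives it. Per the labels' protocols, polyadenylated RNA was selected and sequenced on a HiSeq2500 as paired 125-base reads. Per the submitters' processing notes, TopHat2 2.1.0 and TAIR10 were used. The authors deposited 1 table of RPKM values, already normalised for gene length and library size, for 33323 loci in the 6 libraries. Per the labels' protocols, the authors tested differential expression with DESeq; their test results were not analysed here. The counting tool, its strand setting and its treatment of reads with several matches are not given in the sources used here.

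Group and replicate number were read from the column names and the sample labels. Of the loci, 32835 matched by identifier a RefSeq gene table of the assembly TAIR10.1, and 488 did not. That table gave gene names, biotypes, overlaps and the order of genes along a chromosome. Its coordinates are not printed, because the assembly differs in name from the one the authors used. Places are therefore given by locus identifier, whose first digit names the chromosome.

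RPKM values of a library rise in fixed steps, because each stands for a whole number of reads. From these steps the depth of each library was computed as 10.8, 6.50 and 9.10 M reads (M for mega) for DD25::IaaH 1 to 3. It was 17.8, 8.95 and 9.61 M reads for WT 1 to 3. Of the 31475 loci above 0, 100% had a length between 30 and 20000 bases that gave whole reads within 0.01 reads. As a check on 1000 loci, 99.4% had such a length below 1.5 times their exon length, against 0% when the steps were shifted by 3%. A floor of 3 reads for a gene of 1 kb ranged from 0.169 RPKM in WT 1 to 0.462 RPKM in DD25::IaaH 2. Floors and intervals cover counting error only.

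Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested, which left 20880 genes. Values were transformed to log2(RPKM + 0.5). Linear models were fitted with limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend, a genotype term and no other covariate. Tests were two-sided, adjusted with Benjamini and Hochberg's method, and called at an adjusted p under 0.05. Log2 fold changes are DD25::IaaH minus WT, with standard errors (SE), and RPKM values are means with standard deviations (SD). All adjusted p-values of single genes are from this limma fit unless another is named.

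The authors' unit is RPKM, so no count model was used for the main test. The test was run on 20 simulated sets drawn from the real means and depths with a dispersion of 0.05, each with 200 changed genes. It recovered 93.4% of genes changed by a log2 fold of 2 and 25.2% of those changed by 1, with 0 calls in the wrong direction. False calls made up 11.7% of its calls on simulated data, above the 5% aimed at, and 5.02% with limma voom on whole reads rebuilt from the RPKM steps. The simulation used the same dispersion for every gene and fewer changed genes than were called in the real data. The shares recovered and the false calls may therefore differ in the real test.

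Before the data were examined, 19 gene lists with 380 members, the main test, most alternatives and the rule for naming genes were fixed. Of the members, 376 were kept and 307 were tested; members whose locus the reference names differently were dropped. Lists with at least 5 tested members were compared with all other tested genes by limma's camera, with a preset inter-gene correlation of 0.01. Their p-values were adjusted over the 19 lists. An estimated correlation and limma's fry, which asks whether a list's genes moved one way on balance, were alternatives. With 3 libraries per group, camera with an estimated correlation has little power. Calls were also counted with p-values adjusted over each list alone.

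The rule named the 10 genes with the greatest absolute log2 fold change in each direction, among called genes with separate groups and a mean of at least 1 RPKM. It also named up to 4 tested members of each list in order of adjusted p, and 5 genes whatever their values. These were AT3G04540 (DD25), PHE1, AGL62, YUC10 and TAR1. Of each list, members are given in the order of adjusted p, and a few results are not reported here. Where a group held 0 reads of a gene, the fold is a bound against a floor of 3 reads over the group. With 1 to 3 reads, the ratio is given with its 95% counting interval.

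Alternatives changed the pseudocount to 0.1 or 1, dropped the filter or raised it to 2, and scaled the libraries by median of ratios or quantiles. Others left out the variance trend, made it robust, weighted libraries, added the replicate number as a block, or left out each library in turn. Chosen after seeing the data were voom, a covariate for a split of the libraries by clock genes, and the subtraction of median pseudogene values. Fits to genes outside the locus ranges described with the results, and fits without WT 1 and WT 2 together, were also chosen then. Without WT 1 and WT 2, the single remaining WT library is assumed to vary like the DD25::IaaH libraries.

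Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads are not assigned to transcripts or strands by the table, so genes with near-identical copies or overlapping neighbours are uncertain. The IaaH transgene has no row in the table and was not measured.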

Results

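Whole seeds of Arabidopsis thaliana at 6 days after pollination were profiled in 3 WT and 3 DD25::IaaH libraries. The rebuilt depth was lowest in DD25::IaaH 2, at 6.50 M reads (M for mega), and highest in WT 1, at 17.8 M reads. The first principal component held 68.4% of the variance and separated the genotypes, and the second held 12.0% and set WT 3 apart from WT 1 and WT 2. Correlations across genes, which are not independent replicates, were 0.958 to 0.978 within a genotype and 0.883 to 0.917 between them. WT 1 and WT 2 had reads on 82.1% and 63.8% of annotated pseudogenes, against 21.3% to 32.9% in the other 4 libraries. The locus AT2G01021 held between 19.5% and 30.6% of the summed RPKM of a library.

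The comparison asked which transcripts differ in seeds that carry the auxin-producing transgene, in a study of how auxin affects the formation of cells in the endosperm. In DD25::IaaH seeds 14 of 17 type I MADS-box genes, 10 of 27 endosperm regulators and imprinted genes, 9 of 23 seed storage genes and 6 of 16 seed coat flavonoid genes rose. Of mitotic genes 8 of 26 fell, of cytokinesis genes 4 of 17, of photosynthesis genes 7 of 22, of ARF genes 2 of 15 and of embryo patterning genes 1 of 19. Over all tested genes 8.25% were called higher and 6.72% lower, so 1 of 19 was no excess. In the lists named here 2 storage genes and 1 flavonoid gene fell, and 2 photosynthesis genes rose. These lists passed camera with its preset correlation, and none passed with an estimated correlation, where the smallest adjusted p was 0.435. With 3 libraries per group the estimated correlation rests on few residual degrees of freedom, and that test has little power. Neither the passes nor the misses settle whether a list moved. Outside the locus ranges described with the lower genes, the storage and photosynthesis lists had adjusted p of 0.805 and 0.106, and the flavonoid list had 0.403 without WT 1 and WT 2. Without WT 3 the cytokinesis, ARF, embryo patterning and storage lists had adjusted p of 0.0635, 0.0778, 0.0635 and 0.0635, and with fry 0.0697, 0.0898, 0.0898 and 0.243. The flavonoid and photosynthesis lists had 0.143 and 0.0898 with fry. The embryo patterning list was also lost without WT 1, WT 2, DD25::IaaH 1 or DD25::IaaH 3 and under median-of-ratios and quantile scaling. PHE1, an imprinted MADS-box gene of the endosperm, rose from 3.502 ± 1.24 RPKM in WT to 76.5 ± 19.4 RPKM in DD25::IaaH (SD, n = 3). TES, a kinesin needed for cytokinesis in pollen mother cells, fell from 11.8 ± 1.93 to 3.46 ± 0.511 RPKM (SD, n = 3). The auxin response list as a whole did not pass its test.

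Of 20880 tested genes, 3127 passed the limma test, 1723 of them higher and 1404 lower in DD25::IaaH. An absolute log2 fold change of at least 1 was found for 1867 of these, 1103 higher and 764 lower. The groups did not overlap for 6952 genes (33.3%), where chance gives 10%. The count of calls was 2059 without WT 1, 1978 without WT 2, 1912 without DD25::IaaH 1 and 2015 without DD25::IaaH 3. It was 1063 without both WT 1 and WT 2, the libraries with reads on most pseudogenes, and 1434 when the test was run again on genes outside the locus ranges described with the lower genes.

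By the fitted log2 fold change, which the pseudocount shrinks for genes with few reads, AT4G32110 came first among the rises, from 3.23 ± 0.811 to 786 ± 243 RPKM (SD, n = 3), a log2 fold change of 7.70 ± 0.24 (SE) with an adjusted p of 5.38e-07. AT2G04622 had no read in any WT library and 89.1 ± 26.6 RPKM in DD25::IaaH (SD, n = 3), at least 274-fold higher against the floor over the group. AT4G19239 had 1 read in WT, and the ratio was 617 with a counting interval of 110 to 24407. AT5G55131 had 3 reads in WT, and the ratio was 250 with an interval of 85.1 to 1217. LCR20, LCR38 and LCR35 belong to the LCR family of small cysteine-rich proteins, whose members are similar in sequence. LCR20 rose from 2.095 ± 0.629 to 242 ± 85.5 RPKM and LCR38 from 7.55 ± 6.15 to 526 ± 106 RPKM (SD, n = 3), and LCR35 had a log2 fold change of 6.21. The others were AT2G14846, AT5G50050 and the retroelement SADHU3-2, with log2 fold changes of 6.84, 6.75 and 6.19. Of the 10, LCR20 and LCR35 lay outside the locus ranges described with the lower genes.

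The 10 genes with the lowest fitted log2 fold changes were close to absent in DD25::IaaH. The retroelement SADHU1-1 fell from 209 ± 43.6 to 0.293 ± 0.267 RPKM (SD, n = 3), a log2 fold change of -8.09 ± 0.27 (SE) with an adjusted p of 6.58e-07. HSD2, a steroid dehydrogenase-like gene, fell from 227 ± 201 to 0.369 ± 0.071 RPKM (SD, n = 3). Its neighbour, the snoRNA gene AT3G47348, had no read in DD25::IaaH and was at least 85.8-fold lower. AT3G28899, also without a read, was at least 187-fold lower. AT2G04380 had 3 reads in DD25::IaaH and a ratio of 0.00256, with an interval of 0.000528 to 0.00751. It overlaps AT2G04378, another of the 10, so their reads cannot be told apart here. The others were AT2G15292, the signal recognition particle RNA gene AT7SL-1, AT5G49440 and AT5G48412. Some WT values differed much by library. In WT 1 to 3 AT2G15292 had 554, 142 and 94.3 RPKM, HSD2 457, 138 and 84.6 RPKM and AT7SL-1 230, 135 and 50.4 RPKM. AT3G47348 had 122, 110 and 105 RPKM. Summed snoRNA was 1665, 978 and 489 RPKM in WT 1 to 3 and 347 to 390 RPKM in DD25::IaaH. Every WT library still lay above every DD25::IaaH library for each of the 10 genes.

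By a rule chosen after these values were seen, 81 genes were near-absent in DD25::IaaH, with every WT library at 3 RPKM or more and every DD25::IaaH library below the lowest WT value divided by 15. None of the 81 was on chromosome 1, which had 5533 tested genes. Chromosome 2 held 19 of them (AT2G02360 to AT2G15292), chromosome 3 held 26 (AT3G16400 to AT3G61020), chromosome 4 held 24 (AT4G01593 to AT4G37320) and chromosome 5 held 12 (AT5G48412 to AT5G66053). Inside these ranges 859 of 7216 tested genes (11.9%) were lower and 631 (8.74%) were higher. The 859 hold the 81 near-absent genes, which lie inside by construction, and 778 others. Outside them 545 of 13664 (3.99%) were lower and 1092 (7.99%) were higher, in the test over all genes. The genes outside include chromosome 1, where 2.57% were lower. On chromosomes 2 to 5, 3.39%, 7.23%, 9.95% and 4.57% were lower outside the ranges, against 18.6%, 11.3%, 12.2% and 10.1% inside. The shares inside include the near-absent genes. On chromosomes 3 and 4 the ranges therefore do not mark the limits of the denser lower calls. The same rule with the genotypes exchanged found 91 genes, 15 of them on chromosome 1.

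**Figure D1:**
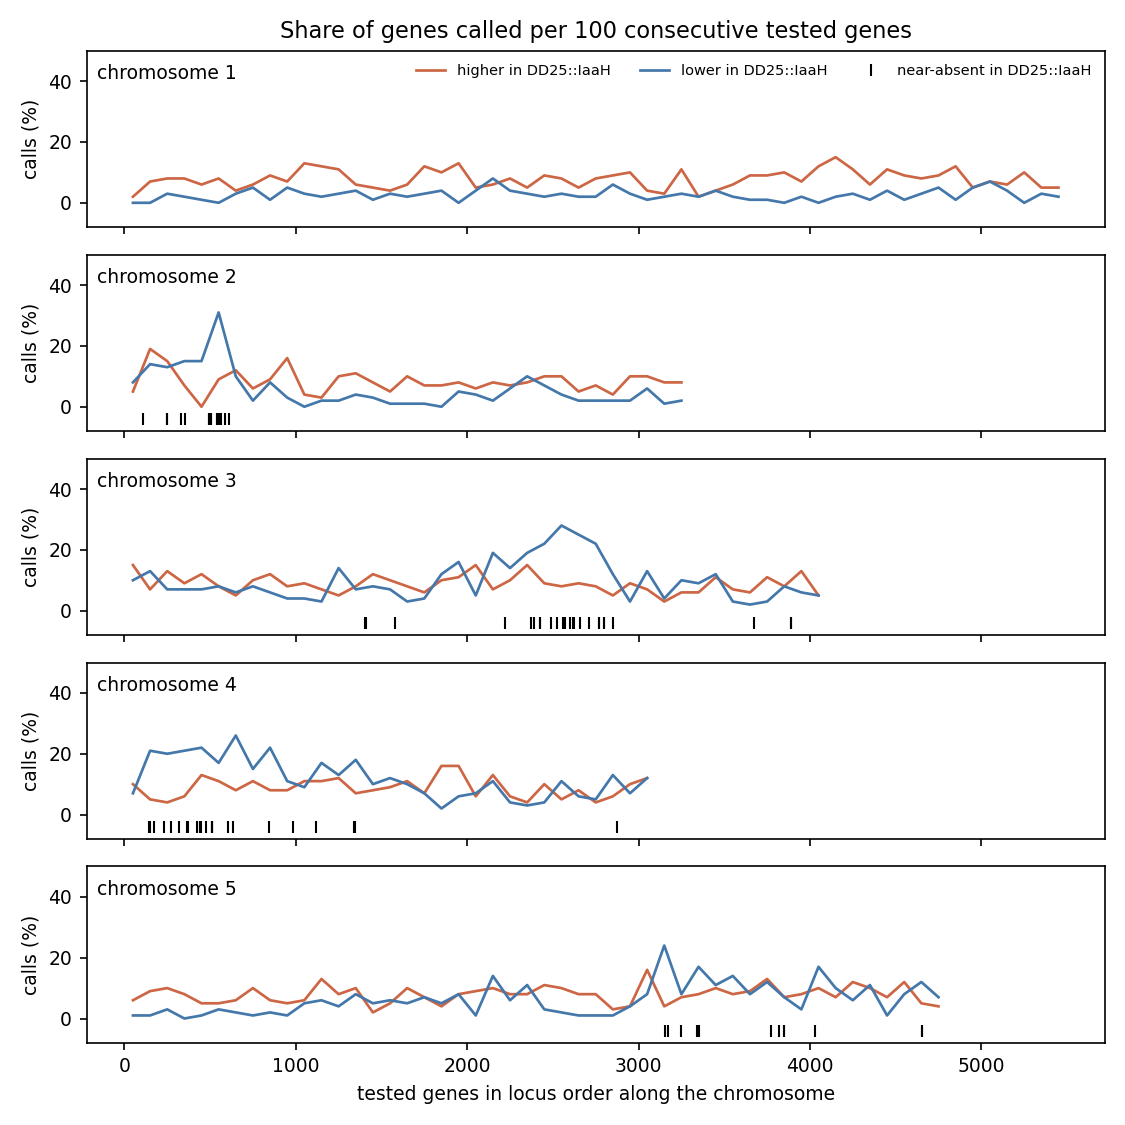
Share of tested genes called higher or lower in DD25::IaaH, in percent, per 100 consecutive tested genes in locus order on each of the 5 chromosomes; ticks mark the 81 near-absent genes. Lower calls were 2.57% of tested genes on chromosome 1 and 11.9% on chromosome 4.

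Type I MADS-box factors, transcription factors of which several act in the central cell and endosperm, gave the strongest list result. Of 17 tested members 14 rose, 0 fell and 3 did not pass, and adjusted over the list alone 14 rose. AGL40, at locus AT4G36590 without a name in the reference, rose from 2.95 ± 0.338 to 97.1 ± 29.2 RPKM (SD, n = 3), a log2 fold change of 4.78 ± 0.21 (SE) with an adjusted p of 2.65e-06. PHE1 had a log2 fold change of 4.28 ± 0.24 (SE) and an adjusted p of 8.33e-06, and it shares sequence with its copy PHE2. AGL91 rose from 2.85 ± 0.121 to 23.0 ± 4.30 RPKM and AGL35, at AT5G26630 without a name in the reference, from 1.69 ± 0.589 to 23.4 ± 12.4 RPKM (SD, n = 3). AGL62, which holds back cell formation in the endosperm, rose from 0.659 ± 0.235 to 4.30 ± 0.665 RPKM (SD, n = 3), with an adjusted p of 0.00091. The list's median log2 fold change was 2.64 and its camera adjusted p 5.20e-12. With an estimated correlation the adjusted p was 0.435. AGL40 and AGL62 lay inside the locus ranges of the near-absent genes, as did 1 other tested member.

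**Figure D2:**
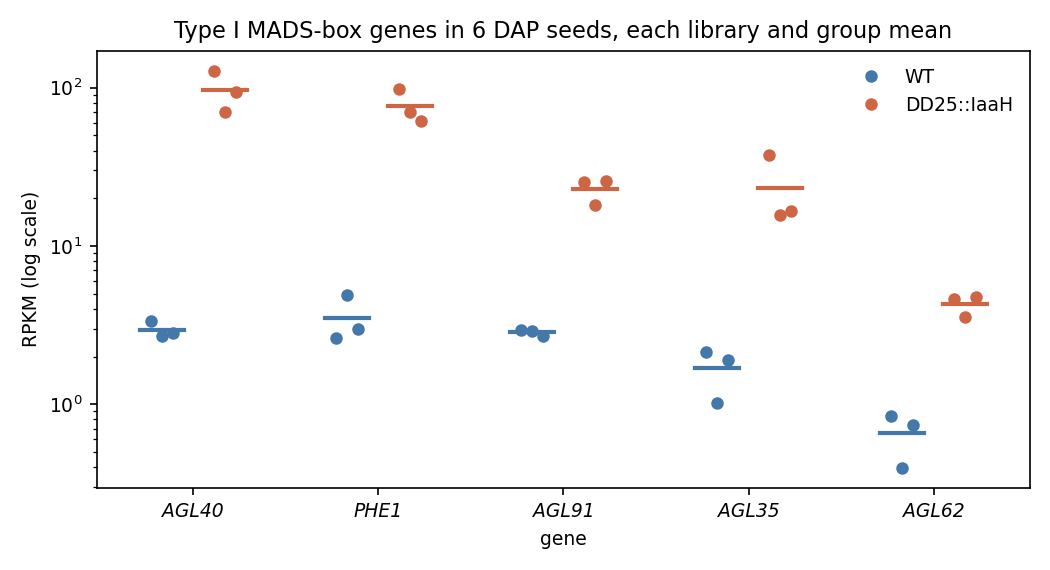
RPKM on a log scale of 5 type I MADS-box genes in each library (points), with the group mean (bars), for 3 WT and 3 DD25::IaaH libraries. Every DD25::IaaH library lay above every WT library for each gene, from 0.659 RPKM on average in WT for AGL62 up to 97.1 RPKM in DD25::IaaH for AGL40.

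Of 27 tested endosperm regulators and imprinted genes, 10 rose, 0 fell and 17 did not pass, and adjusted over the list alone 12 rose. CKX2, a cytokinin oxidase expressed in the endosperm, rose from 1.68 ± 0.343 to 30.7 ± 8.26 RPKM (SD, n = 3), a log2 fold change of 3.82 ± 0.23 (SE) with an adjusted p of 1.24e-05. HDG8, a homeodomain gene, rose from 2.05 ± 1.22 to 21.9 ± 8.38 RPKM and MPC, a poly(A)-binding protein-like gene, from 1.89 ± 1.69 to 29.2 ± 0.984 RPKM (SD, n = 3). The histone methyltransferase-like gene SUVH7 rose from 0.589 ± 0.152 to 3.13 ± 0.775 RPKM (SD, n = 3). Over the list, the median log2 fold change was 0.45 and the list's camera adjusted p 0.00121. With an estimated correlation the adjusted p was 0.435.

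Few auxin response genes were called, and these moved both ways, at close to the share over all tested genes (8.25% higher and 6.72% lower). Of 22 tested members 2 rose, 2 fell and 18 did not pass, with the same counts adjusted over the list alone, and 29 of the list's 51 members were below the filter. GH3.4, an auxin-conjugating enzyme gene, rose from 0.115 ± 0.199 to 4.85 ± 1.98 RPKM and the Aux/IAA gene IAA31 from 74.4 ± 4.34 to 156 ± 29.5 RPKM (SD, n = 3). IAA31 lay inside the locus ranges of the near-absent genes. GH3.3 fell from 9.48 ± 0.438 to 4.96 ± 0.590 RPKM and GH3.2 from 11.1 ± 5.46 to 3.06 ± 0.650 RPKM (SD, n = 3). Across its members the median log2 fold change was -0.20 and the list's camera adjusted p 0.335. Among genes outside the locus ranges of the near-absent genes the list passed as lower, with an adjusted p of 0.0275 over 16 members and a range of 0.0275 to 0.854 over the alternatives. For the whole list the adjusted p was 0.631 with an estimated correlation. GH3.2 lost its call without WT 1 (adjusted p 0.0549) and without DD25::IaaH 3 (0.0608), and without WT 1 and WT 2 together GH3.2 and GH3.3 had adjusted p of 0.266 and 0.160.

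Auxin synthesis and conjugation genes included 3 that rose, 1 that fell and 15 that did not pass, with the same calls adjusted over the list alone. TAR1, an aminotransferase of auxin synthesis, rose from 0.428 ± 0.328 to 3.86 ± 0.850 RPKM (SD, n = 3), with a log2 fold change of 2.27 ± 0.32 (SE) and an adjusted p of 0.00166. UGT74D1, an auxin glucosyltransferase gene, rose from 2.03 ± 0.363 to 6.54 ± 2.17 RPKM and YUC10, a flavin monooxygenase of auxin synthesis, from 3.18 ± 0.101 to 6.98 ± 1.81 RPKM (SD, n = 3). IAMT1, an auxin methyltransferase gene, had a log2 fold change of -0.70. The list's median log2 fold change was -0.02 and its mean 0.17, and its camera adjusted p was 0.706. YUC10 lost its call without DD25::IaaH 1 (adjusted p 0.0543), and IAMT1 without WT 2 (0.0561), without DD25::IaaH 1, 2 or 3 (0.109, 0.0662 and 0.109) and without the variance trend (0.0784). Without WT 1 and WT 2 together, UGT74D1 had an adjusted p of 0.0848 and YUC10 of 0.166.

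Of 15 auxin transport genes, the carrier gene PILS5 alone passed, also adjusted over the list alone. It rose from 0.913 ± 0.171 to 4.79 ± 0.759 RPKM (SD, n = 3), with an adjusted p of 0.000702, and it overlaps AT2G17510. PIN3, an auxin efflux carrier, had a log2 fold change of 0.58 with an adjusted p of 0.0549. Over the list, the median was -0.04, its mean 0.06 and its camera adjusted p 0.880. Of 15 ARF transcription factors, 2 fell and 13 did not pass, with the same counts adjusted over the list alone. ARF4 fell from 9.40 ± 1.42 to 5.85 ± 0.516 RPKM and ARF9 from 6.38 ± 1.38 to 3.59 ± 0.373 RPKM (SD, n = 3). Both lay inside the locus ranges of the near-absent genes. Outside them 0 of 11 ARF genes were called, and the ARF list had a camera adjusted p of 0.0354 there. The median of the ARF list was -0.35 and its camera adjusted p 0.0288, against an adjusted p of 0.581 with an estimated correlation. The ARF list also lost its call without the filter (0.903), with fry (0.0898), without WT 3 (0.0778) and without DD25::IaaH 3 (0.111). The calls of ARF4 and ARF9 were lost without each of WT 1, WT 2 and the DD25::IaaH libraries, with adjusted p from 0.0639 to 0.164, and were also lost without the filter (0.0665 and 0.0872), with the clock covariate (0.0850 and 0.0972) and without WT 1 and WT 2 together (0.468 and 0.524).

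Of 26 tested mitotic cell cycle genes, 0 rose, 8 fell and 18 did not pass, and adjusted over the list alone 11 fell. CDKB1;2, a mitotic cyclin-dependent kinase, fell from 20.9 ± 2.60 to 1.86 ± 0.227 RPKM (SD, n = 3), a log2 fold change of -3.18 ± 0.17 (SE) with an adjusted p of 5.77e-06. MAD2, of the spindle checkpoint, fell from 106 ± 21.0 to 17.5 ± 2.53 RPKM and its partner gene CDC20.1 from 50.3 ± 1.498 to 29.1 ± 6.81 RPKM (SD, n = 3). CDKB1;2 overlaps AT2G38630 and MAD2 overlaps AT3G25990. Across its members the median was -0.40 and the list's camera adjusted p 9.52e-06. With an estimated correlation the adjusted p was 0.517. MAD2 and CDC20.1 lay inside the locus ranges of the near-absent genes, and the list outside them had an adjusted p of 1.08e-05. Without WT 1 and WT 2 together the adjusted p of CDC20.1 was 0.176.

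Cytokinesis and cell plate genes had 4 that fell, 0 that rose and 13 that did not pass, and adjusted over the list alone 7 fell and 1 rose. TES had a log2 fold change of -1.63 ± 0.19 (SE) and an adjusted p of 0.000467. MAP65-3, a microtubule-bundling protein of the phragmoplast, fell from 20.19 ± 0.740 to 12.7 ± 1.16 RPKM (SD, n = 3). TES and MAP65-3 lay inside the locus ranges of the near-absent genes. The list's median was -0.25 and its camera adjusted p 0.0148, against 0.0635 without WT 3, 0.0697 with fry and an adjusted p of 0.581 with an estimated correlation. Without WT 1 and WT 2 together the adjusted p of MAP65-3 was 0.184. Of 15 DNA replication genes, 3 fell and 12 did not pass, with the same counts adjusted over the list alone, and the list's camera adjusted p was 0.459. RNR2A, a ribonucleotide reductase subunit gene, fell from 19.1 ± 0.962 to 12.1 ± 0.993 RPKM and the helicase gene MCM7 from 21.0 ± 3.09 to 14.2 ± 0.675 RPKM (SD, n = 3). RNR2A and MCM7 also lay inside the locus ranges. Outside them the 9 tested members of the DNA replication list had a median log2 fold change of 0.05 and a camera adjusted p of 0.805. RNR2A lost its call without DD25::IaaH 1 (adjusted p 0.0504) and without WT 1 and WT 2 together (0.189). MCM7 lost its call without each library except WT 2, with adjusted p from 0.0683 to 0.109, without the variance trend (0.0644) and without WT 1 and WT 2 together (0.0778).

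Embryo patterning markers had 1 gene that fell among 19 tested, also adjusted over the list alone. It was WOX9, a homeodomain factor of the early embryo, which fell from 15.7 ± 2.07 to 8.14 ± 1.84 RPKM (SD, n = 3), with an adjusted p of 0.0113. SCR, a root patterning factor, had 14.5 ± 0.079 RPKM in WT and 11.2 ± 0.912 RPKM in DD25::IaaH (SD, n = 3) and did not pass. Over the list, the median was -0.29 and the list's camera adjusted p 0.0498, against an adjusted p of 0.581 with an estimated correlation. The list lost its call without WT 1, 2 or 3 and without DD25::IaaH 1 or 3, with adjusted p of 0.0815, 0.0819, 0.0635, 0.0953 and 0.111. It was also lost with a pseudocount of 1 (0.0539), without the filter (0.260), with the filter at 2 (0.0925), with median-of-ratios (0.0525) or quantile scaling (0.0514) and with fry (0.0898). Further losses were with the clock covariate (0.0779), pseudogene subtraction (0.0699) and without WT 1 and WT 2 together (0.268). Without WT 1 and WT 2 together the adjusted p of WOX9 was 0.274.

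Seed maturation and storage genes had 9 that rose, 2 that fell and 12 that did not pass among 23 tested, and adjusted over the list alone 9 rose and 3 fell. SESA3, a seed storage albumin gene, rose from 36.4 ± 31.5 to 342 ± 31.2 RPKM (SD, n = 3), a log2 fold change of 3.603 ± 0.53 (SE) with an adjusted p of 0.00218. Its neighbours and close copies SESA2 and SESA4 rose from 16.8 ± 16.5 to 140.4 ± 39.2 RPKM and from 8.20 ± 9.12 to 104 ± 31.7 RPKM (SD, n = 3). The storage globulin gene CRC rose from 2.85 ± 4.06 to 46.2 ± 33.5 RPKM (SD, n = 3). Across its members the median was 0.69 and the list's camera adjusted p 0.0337, against an adjusted p of 0.631 with an estimated correlation. The list lost its call without WT 3 (0.0635), without DD25::IaaH 2 (0.1003), with library weights (0.0708) and with fry (0.243). With robust variance SESA2, SESA4 and CRC had adjusted p of 0.0618, 0.0629 and 0.0695. These 4 genes and 8 other tested members lay inside the locus ranges of the near-absent genes, and the list outside them had an adjusted p of 0.805.

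Seed coat flavonoid markers had 6 that rose, 1 that fell and 9 that did not pass among 16 tested, and adjusted over the list alone 11 rose and 1 fell. TT10, a laccase gene that acts late in the browning of the seed coat, fell from 578 ± 56.6 to 259 ± 24.7 RPKM (SD, n = 3), with an adjusted p of 0.00054. TT2, a regulator of proanthocyanidin synthesis, rose from 21.7 ± 6.25 to 40.8 ± 4.71 RPKM and BAN, an enzyme gene of the same pathway, from 499 ± 90.5 to 835 ± 75.8 RPKM (SD, n = 3). The list's median was 0.58 and its camera adjusted p 0.00339, against an adjusted p of 0.622 with an estimated correlation. It was 0.143 with fry and 0.403 without WT 1 and WT 2 together, the libraries with reads on most pseudogenes. TT2 lost its call without WT 2 (adjusted p 0.0545) and DD25::IaaH 3 (0.0606), and BAN without WT 1, WT 2, DD25::IaaH 2 and DD25::IaaH 3 (0.0531 to 0.0667). TT2 and BAN had adjusted p of 0.239 and 0.257 without WT 1 and WT 2 together. None of the 9 seed coat mucilage markers passed the limma test, also adjusted over the list alone, and the list's camera adjusted p was 0.880.

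Photosynthesis genes, which mark green tissue, had 7 that fell, 2 that rose and 13 that did not pass, and adjusted over the list alone 10 fell and 3 rose. LHCB2.1, a light-harvesting protein gene, fell from 183 ± 25.2 to 97.4 ± 13.7 RPKM and CAB3, of the same function, from 460.1 ± 112 to 236 ± 22.3 RPKM (SD, n = 3). Both have close copies among which reads could be shared. Over the list, the median was -0.31 and the list's camera adjusted p 0.00667, against an adjusted p of 0.581 with an estimated correlation. It was 0.0898 with fry and 0.106 for genes outside the locus ranges of the near-absent genes. CAB3 lost its call without DD25::IaaH 1 (adjusted p 0.0526).

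Cell wall loosening and pectin genes moved both ways, with 1 that rose, 4 that fell and 12 that did not pass, and adjusted over the list alone 1 rose and 6 fell. XTH24, a xyloglucan-modifying enzyme gene, rose from 100.3 ± 28.4 to 259 ± 24.2 RPKM and the expansin gene EXPA4 fell from 28.5 ± 6.75 to 14.8 ± 1.48 RPKM (SD, n = 3). The list's camera adjusted p was 0.107, and among genes outside the locus ranges of the near-absent genes it passed as lower at 0.0106. Its values over the alternatives ranged from 0.0106 to 0.581, the value with an estimated correlation. The adjusted p of EXPA4 was 0.173 without WT 1 and WT 2 together.

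The cytokinin response list also holds the synthesis genes IPT4 and IPT8. Of its 8 tested members 4 rose and 4 did not pass, with the same counts adjusted over the list alone. Inside the locus ranges of the near-absent genes lay 4 of the 8, IPT4 and ARR6 among them. The list was not tested outside the ranges. IPT4, a cytokinin synthesis gene, rose from 0.0892 ± 0.155 to 2.75 ± 0.652 RPKM, with an adjusted p of 0.00123, and the response regulator gene ARR6 from 0.170 ± 0.103 to 2.17 ± 0.927 RPKM (SD, n = 3). Across its members the median was 0.78 and the list's camera adjusted p 0.0889, against an adjusted p of 0.517 with an estimated correlation. It passed as higher without WT 2 (0.0457), without WT 1 and WT 2 together (0.0212), without the filter (0.0170), without the variance trend (0.0396) and with fry (0.0101). ARR6 lost its call without DD25::IaaH 1 (adjusted p 0.0504), DD25::IaaH 3 (0.0524) and WT 1 with WT 2 (0.0976), and it overlaps AT5G62910.

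Jasmonate and pathogen response genes had 2 that fell and 7 that did not pass, and adjusted over the list alone 3 fell. OPR3, an enzyme gene of jasmonate synthesis, fell from 10.96 ± 1.23 to 5.32 ± 0.630 RPKM (SD, n = 3), and the list's camera adjusted p was 0.371. VSP1, a jasmonate-induced storage protein gene, fell from 3.70 ± 1.89 to 1.01 ± 0.527 RPKM (SD, n = 3). VSP1 lost its call without WT 1, WT 2, DD25::IaaH 2 and DD25::IaaH 3 (adjusted p 0.0807 to 0.122), without the filter (0.0595) and with voom (0.0633). VSP1 and OPR3 had 0.407 and 0.0591 without WT 1 and WT 2 together.

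Of 5 heat shock genes, HSP90.1, a chaperone gene, alone passed, also adjusted over the list alone. It rose from 12.2 ± 1.40 to 26.3 ± 1.40 RPKM (SD, n = 3), and the list's camera adjusted p was 0.459. Of 6 gibberellin metabolism genes, GA3OX4, a gibberellin synthesis gene, alone passed, also adjusted over the list alone. It rose from 5.03 ± 2.75 to 19.0 ± 5.96 RPKM (SD, n = 3), with an adjusted p of 0.0149, and the list's camera adjusted p was 0.880. Its call was lost without DD25::IaaH 1 (adjusted p 0.0617). The gene DD25 itself, AT3G04540, was below the filter, with 0.125 ± 0.217 RPKM in WT and 0.247 ± 0.427 RPKM in DD25::IaaH (SD, n = 3), so no difference was detectable at this depth.

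**Figure D3:**
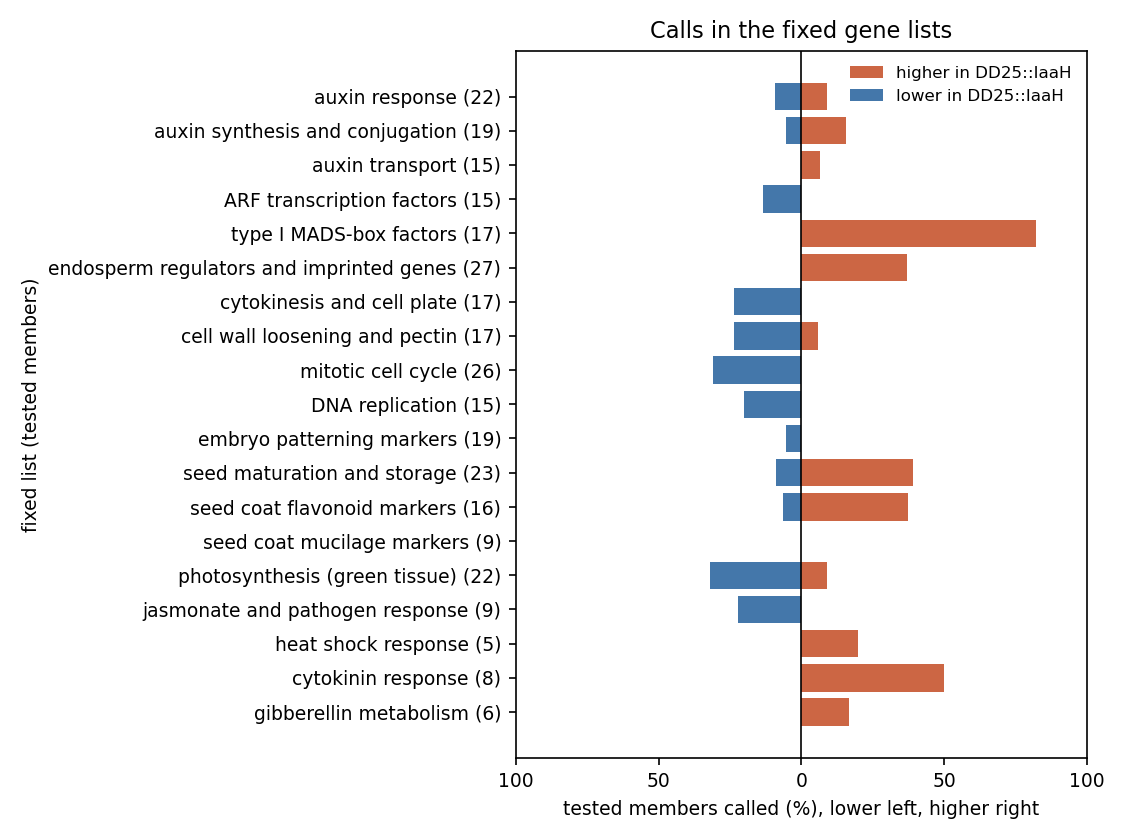
Percent of tested members of each of the 19 fixed lists called lower (left) or higher (right) in DD25::IaaH, with the number of tested members in brackets. The type I MADS-box list had the most higher calls, 14 of 17, and the mitotic list had 8 lower calls of 26.

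By camera with the preset correlation, 9 of the 19 lists passed, 4 as higher and 5 as lower. With an estimated correlation 0 passed, the smallest adjusted p was 0.435, 2 lists had an unadjusted p under 0.05, and fry passed 4. Without WT 3, 5 lists passed.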

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

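The voom, clock-covariate, pseudogene-subtraction, outside-range and WT 1 with WT 2 settings were tests chosen after the results were seen. Of 3127 calls (1723 higher, 1404 lower), leaving out single libraries gave 1912 to 4133 (1012 to 2223 higher, 850 to 1910 lower), with 5 to 9 lists past the threshold and an auxin response p of 0.178 to 0.489. A fold of at least 1 on the log2 scale gave 1867 (1103 and 764), since it adds a condition. Fewer genes tested, outside the locus ranges, gave 1434 (971 and 463) and an auxin response p of 0.0275, whose cause was not tested. Fewer samples, without WT 1 and WT 2, gave 1063 (684 and 379). The other settings gave 2429 to 4260 calls. The balance of directions depended on scaling, with 1595 higher and 1502 lower under median-of-ratios and 1523 higher and 1650 lower under quantile scaling. Lists past the threshold numbered 0 with an estimated correlation and 4 with fry. The replicate block gave 2429 calls (1368 and 1061) and 8 lists, with the embryo patterning list at 0.0527, and 10 called named genes did not pass. Same-numbered samples deviated with correlations of -0.08, -0.03 and -0.10, and no sample deviated most like its own number. These values showed no pairing by number, but with 3 libraries per genotype they cannot exclude it. Lists not called in the main test turned direction, at adjusted p, as follows, and the cause was not tested. Auxin transport did so without the filter (0.903), without WT 2 (0.933) or DD25::IaaH 3 (0.876; 0.533 to 0.933 over single libraries), with fry (0.481) and without WT 1 and WT 2 (0.854), as did auxin synthesis in the last setting (0.854). DNA replication turned outside the ranges (0.805), gibberellin without WT 1 (0.993; 0.747 to 0.993), and mucilage without the filter (0.903), with library weights (0.960) and without WT 3 (0.764; 0.719 to 0.980). Log2 fold changes of uncalled genes turned to -0.028 for TTG2 and -0.076 for MYB5 without WT 1 and WT 2, and to 0.45 for HSP17.6II without DD25::IaaH 3 (-0.74 to 0.45 over single libraries). Of 76 called named genes, 42 kept their call and direction in every setting that gave them a value, and 52 when each library was left out. Depth limited genes near 3 reads.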

Other observations

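The tests of gene families by name, and all tests of explanations below except the splits of the libraries and the harvest-time test, were chosen only after the results were seen.

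Gene families outside the fixed lists also differed. Among 131 name families with at least 10 tested members, small cysteine-rich protein genes stood out. Of 52 LCR genes 28 were higher and 8 lower, an odds ratio of 13.2 for higher calls with a one-sided Fisher's exact adjusted p of 5.92e-15. Of 12 SCRL genes, named for likeness to the pollen coat protein of self-incompatibility, 11 were higher, with an adjusted p of 1.71e-09. The directions held under median-of-ratios and quantile scaling, with 28 and 29 LCR and 11 and 11 SCRL genes called higher. Inside the locus ranges of the near-absent genes lay 26 of the LCR and 6 of the SCRL genes. Outside them 15 of 26 LCR genes were higher and 1 lower (adjusted p 1.38e-08), and 5 of 6 SCRL genes were higher (0.00158). Members of a family are similar in sequence and are not independent. ARI, GSTF and TET genes were enriched among higher calls and RLP and HB genes among lower calls, with adjusted p from 0.0335 to 0.0377. Under both scalings GSTF and TET each had 4 higher calls in place of 5, and the enrichment was not tested again there. Outside the locus ranges none of these 5 families passed, with adjusted p from 0.126 to 0.581.

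The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3127 genes and the highest of the others 0, so 1 of the 10 splits, the real one, gave that many.

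The 81 genes near-absent in DD25::IaaH lay in ranges on chromosomes 2 to 5. Low depth is argued against: 104412 reads were expected and 1137 found, a ratio of 91.8 that missed the bound of 100 set first, but the median gene expected 477 reads, a measure added after that. A change in cell types or a response to the transgene would follow expressed genes over the chromosomes, yet chromosome 1 held 0 where matched draws gave a 95% range of 14 to 29. Chromosome segments from another accession are a candidate explanation, against which stands the Col-0 background that the labels give for both genotypes. Without the near-absent genes that set the ranges, lower calls had an odds ratio inside of 2.95 (95% interval 2.630 to 3.3001). Higher calls had 1.12 (1.01 to 1.24). In 1000 shuffles over all genes with ranges redrawn, 95% of the odds ratios of lower calls were 0.843 to 1.19. Such shuffles also place genes on chromosome 1, which the real ranges leave out, so they are an unlike setting for the 2.95. Within chromosomes 2 to 5 the odds ratio of lower calls was 1.91 (1.66 to 2.19), with no shuffle range for it. Reads lost to sequence differences may add to the lower calls inside. The median log2 fold change of other genes inside lay -0.087 from that outside (95% interval -0.10 to -0.07). No sequence was at hand to test either explanation.

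Clock genes split the libraries across genotypes, with the glycine-rich protein gene GRP7 at 3174, 3670 and 648 RPKM in WT 1 to 3 and 2946, 868 and 679 RPKM in DD25::IaaH 1 to 3. Genotype would put all DD25::IaaH libraries on one side of WT, but on 9 other clock genes the evening minus morning log2 difference was 2.37 in DD25::IaaH 1, between WT 1 (1.43) and WT 2 (2.45). On the genes first seen it was 3.196, between WT 3 (1.83) and WT 1 (3.87), so the place between WT 1 and WT 2 that was required first was missed, and the 9 genes were taken after that. Single morning genes did part by genotype. CCA1 had 4.08, 2.00 and 5.06 RPKM in WT 1 to 3 and 6.87, 7.09 and 9.61 RPKM in DD25::IaaH 1 to 3. RVE2 had 3.90, 3.53 and 2.55 RPKM in WT and 1.33, 1.26 and 2.02 RPKM in DD25::IaaH. Their limma adjusted p were 0.0466 and 0.0452, and no other of these clock genes was called. A genotype difference in single clock genes is therefore not excluded. Harvest at different times of day is a candidate explanation, as the 9 genes parted WT 1, WT 2 and DD25::IaaH 1 from the other libraries by 1.11, and the labels give no harvest time. Over all tested genes the split was not seen. There the deviations of DD25::IaaH 1 from its genotype mean had correlations of -0.080 with those of WT 1, 0.034 with WT 2 and 0.042 with WT 3. With the split as a covariate 2539 genes passed.

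WT 1 and WT 2 had reads on 82.1% and 63.8% of pseudogenes. Depth was argued against, since thinned to 6.50 M reads they still had 74.0% and 60.3%, and the other libraries 21.3% to 29.6%. Genomic DNA in these libraries may account for it: in WT 1 the mean of tRNA genes gained 0.700 RPKM and that of pseudogenes 0.507 RPKM, a ratio of 1.38, and in WT 2 the gains were 0.265 and 0.133 RPKM, a ratio of 1.997. Summed snRNA, at 1736 and 704 RPKM in WT 1 and WT 2 and 40.1 to 120.2 RPKM elsewhere, was also higher, so unspliced or unselected RNA, which was not tested, stays open. No biological explanation of the pseudogene reads was tested.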
